A study of Mus musculus with 6 samples.

How the data were processed

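Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on mouse embryonic fibroblasts (MEFs) of the C57BL/6 strain, primary connective-tissue cells grown from embryos. Cells had either been exposed to a chemical combination called 6TCF in the labels or left untreated, and both were sampled on day 6. Libraries titled H3K4me3, H3K27me3 and input DNA were made from each condition, which gives 6 libraries and 1 library per group. Trimethylation of histone H3 at lysine 4 is a mark of active or poised promoters. Trimethylation at lysine 27 is a mark deposited by Polycomb repressive complexes. Input DNA is sheared chromatin that was not immunoprecipitated. The titles and the antibody field of the labels disagree: for the libraries titled H3K4me3 the antibody field names H3K4me2, and for those titled H3K27me3 it names H3K4me1. The titles and the extraction protocol name H3K4me3 and H3K27me3, so these names are used here, and the identity of the antibodies stays unsettled.

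Per the labels' protocols, chromatin was fixed with formaldehyde and sheared to an average of 600 bp before precipitation. The submitters' processing notes name CASAVA 1.7, Bowtie2 2.2.5, MACS 1.4.3, HOMER and the mouse build mm9, with no role or order. The calling threshold, the tool that called each list and the control used for calling are not given in the sources used here. The deposited files are 1 peak list per library, and each input library has a list of its own. Each row gives a chromosome, a start, an end and a constant strand sign. No height, score, fold or p-value per peak and no read number was in the files used here, so sequencing depth is unknown and peak strength could not be compared. Peak width, the number of bases from the first to the last position of a peak, is the only quantity per peak. A peak's presence and its width both depend on depth, antibody yield and threshold, and a region without a listed peak is not shown to lack the mark.

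Peak sets were compared by overlap. A peak was called shared when it overlapped a peak of the other condition by at least 1 bp. Overlaps were computed in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and the counts were checked against bedtools 2.31.1. Shares carry 95% Wilson intervals, which treat peaks as independent and cover counting error only. With 1 library per group there is no replicate error and no test of the treatment, and no p-value is given. The background was taken from the input lists, and peaks that overlap an input peak of either condition are stated where they matter. Widths were compared in pairs, defined as 1 treated and 1 untreated H3K4me3 peak that overlap each other and no other H3K4me3 peak. The comparison of pair widths at H3K27me3 peaks, the comparison of H3K4me3 peaks in 1 list only with H3K27me3 peaks, the grouping of neighbouring peaks and the width classes were not part of the design and were chosen after the lists had been explored. A pair was assigned an H3K27me3 peak only when that peak overlapped the part common to both members and overlapped no input peak, so that a wide peak in 1 condition did not favour the assignment. Medians of such pairs were set beside 10000 random sets of pairs matched on the decile of mean log2 width, and their intervals come from 2000 bootstrap draws. Overlap of marks was set beside 1000 random placements of the same peaks on their own chromosomes, which ignore assembly gaps. Groups of at least 3 peaks in 1 list only, each no more than 20 kb from the next, were set beside 1000 draws of as many peaks from the same list, matched on width decile. These percentiles describe the libraries and are not p-values, because peaks are not replicates.

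The overlap and width steps were tested on simulated data made from the untreated H3K4me3 list of 17168 peaks. All 300 added and all 200 removed peaks were found. The added peaks were placed clear of all others, and changed peaks were kept from reaching the next peak. These counts therefore check the counting only, and no loss of peaks through depth or threshold was simulated. For 400 peaks widened 1.2-fold the median log2 width ratio found was 0.27, against 0.26 put in, and 100% of 1000 matched random sets lay below it. An unwidened set lay above 25.8% of its random sets. The widened peaks were picked at random and given noise independent of their width. The width result therefore checks the computation only, and no library effect tied to narrow peaks was simulated.

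The design was fixed before the data were examined. It included a comparison of promoter states, lists of marker genes and a ranking of peaks by score. Peaks could not be assigned to genes, because the gene table at hand is of another build than the files, so positions are given in mm9 with no gene, exon or promoter annotation, and the gene lists were not evaluated. The rule for named items was therefore applied to peaks: the 5 in each list only, per mark and direction, that overlap no input peak. They were ranked by width in place of the score. Regions named for other reasons were chosen after their values were seen, and the region on chromosome 6 that is drawn was chosen after several other windows had been viewed. Alternatives covered the overlap that counts as shared, peaks up to 1 kb apart, removal of peaks that overlap an input peak and, added later in place of score thresholds, removal of the narrowest 25% of each list and equal numbers of widest peaks. Coordinates are 1-based.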

Results

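The study compared the positions of H3K4me3 and H3K27me3 in 6TCF-treated and untreated MEFs on day 6, with input DNA of each condition as background. The series title places the treatment in work on turning fibroblasts towards other lineages with chemical combinations. The antibody field of the labels names other H3 marks than the titles (H3K4me2 and H3K4me1), and the titles were followed. Each of the 6 groups held 1 library, so no difference between conditions has a replicate check. The H3K4me3 lists held 18185 peaks in treated and 17168 in untreated cells and covered 40.6 and 40.0 Mb. The H3K27me3 lists held 821 and 1242 peaks and covered 0.173 and 0.367 Mb. The input lists held 604 peaks in treated and 740 in untreated cells. Read depth was not given, and its effect on these numbers is unknown. No gene annotation of the mm9 build was used here, so every region is named by position.

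H3K4me3 peaks were largely at the same places in treated and untreated cells. Of the treated peaks 89.8% (95% interval 89.4 to 90.2) overlapped an untreated peak, and of the untreated peaks 95.3% (94.9 to 95.6) overlapped a treated one. A total of 1854 peaks were in the treated list only and 812 in the untreated list only. Peaks in 1 list only were narrow: their median width was 863 bp in treated and 838 bp in untreated cells, against 2152 and 2173 bp for shared peaks. In the ranking of widths within its own list, the median treated-only peak stood at percentile 8.85 and the median untreated-only peak at 7.98. The excess of treated-only peaks lay in the narrow classes. Among peaks of up to 1 kb, 1296 of 2534 treated peaks (51.1%) and 545 of 2325 untreated peaks (23.4%) were in 1 list only. Among peaks of over 2 to 6 kb the numbers were 70 of 9044 (0.774%) and 44 of 9021 (0.488%). When the same number of widest peaks was kept in both lists, 1226 peaks were treated-only and 1195 untreated-only. Lists of equal length give nearly equal numbers by construction.

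**Figure D1:**
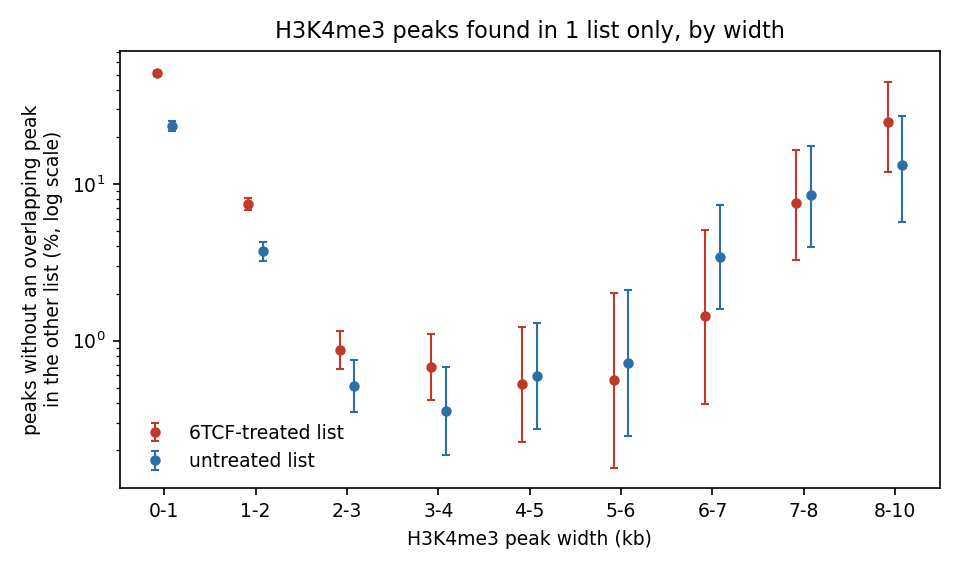
Share of H3K4me3 peaks with no overlapping peak in the other condition (log axis, percent) by peak width in kb, for the treated (red) and untreated (blue) lists, 1 library each. Points are shares and bars 95% Wilson intervals. The share falls from 51.1% and 23.4% up to 1 kb to 0.527% and 0.595% at 4 to 5 kb, and is 25% and 13.2% over 8 kb.

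Wide H3K4me3 peaks in 1 list only were few, and their share of all peaks of like width rose near the top of the width range. The widest treated-only peaks were at chromosome 14, 106289911 to 106298940 (9030 bp), chromosome 5, 22935561 to 22944567 (9007 bp), chromosome 12, 34640400 to 34649338 (8939 bp), chromosome 19, 59530355 to 59539045 (8691 bp), and chromosome 3, 145308833 to 145317402 (8570 bp). The nearest untreated peak was between 1.87 kb (chromosome 12) and 67.8 kb (chromosome 3) away. The widest untreated-only peaks were at chromosome 10, 119906916 to 119915901 (8986 bp), chromosome 18, 69503035 to 69511986 (8952 bp), chromosome 9, 81520853 to 81529578 (8726 bp), chromosome 13, 63340366 to 63349071 (8706 bp), and chromosome 1, 170355157 to 170363618 (8462 bp). The nearest treated peak was between 31.9 kb (chromosome 1) and 227 kb (chromosome 9) away. Neither list held a peak wider than 9151 bp, and over 7 kb the share of peaks in 1 list only was 12.2% (11 of 90) in treated and 10.2% (11 of 108) in untreated cells. A partner wider than the widest listed peak would be missing from the lists, so the absence of a partner for these regions is uncertain.

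Peaks in 1 list only lay close together more often than matched draws from the same list, in a comparison chosen after the lists had been explored. Treated-only peaks formed 12 groups of at least 3, against a median of 6 and a maximum of 14 in 1000 draws, and 98.3% of draws had fewer. Untreated-only peaks formed 4 groups, against a median of 0 and a maximum of 5, and 99.2% of draws had fewer. Among these 4 was the mitochondrial genome, where both input lists also held peaks. Without mitochondrial peaks there were 3 groups, against a median of 0 and a maximum of 3, and 98.2% of draws had fewer. The draws were matched on width decile only. A missing partner wider than the widest listed peak could leave several neighbouring peaks in 1 list only, and this was not tested. Untreated peaks lay inside 7 of the 12 treated-only groups. The longest treated-only group had 4 peaks of 674 to 1739 bp on chromosome 8, 74178314 to 74218128, with 2 untreated peaks between them. The group on chromosome 6, 52100510 to 52126921, had 3 peaks of up to 4114 bp with no untreated peak between them. On chromosome 6, over 52100510 to 52267275, a stretch chosen after its peaks were seen, the treated list held 14 H3K4me3 peaks, 5 of them treated-only, and the untreated list held 9, all shared. In untreated cells a group of 4 peaks of 2239 to 8706 bp lay on chromosome 13, 63340366 to 63383112, where no treated peak was listed. Its 8706 bp peak is among those over 7 kb for which the absence of a partner is uncertain. A treated peak that joined its last members, from 63373404 to 63383112, would also be wider than the widest listed peak. On chromosome 6 the same holds for an untreated peak that reached from 52100510 to 52111598 or from 52152910 to 52164214. The absence of untreated partners for these treated-only peaks is therefore uncertain too.

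**Figure D2:**
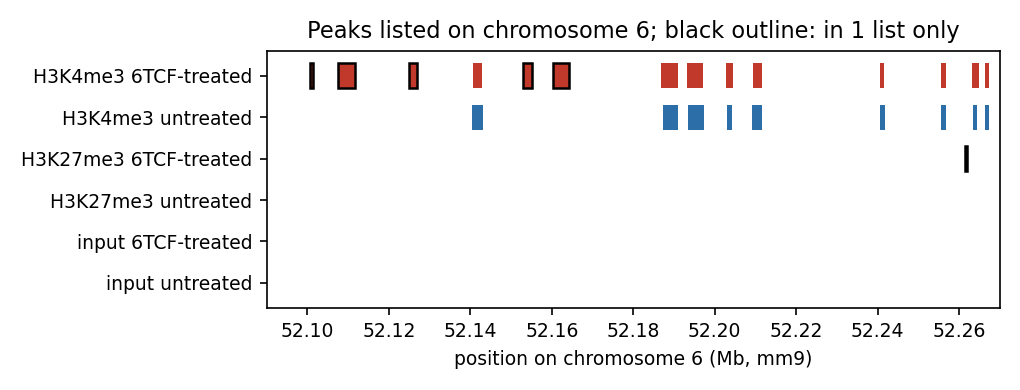
Peaks of all 6 lists along chromosome 6 (position in Mb, mm9), 1 row per library, with red for treated and blue for untreated cells. A black outline marks peaks in 1 list only. The treated H3K4me3 list has 14 peaks, 5 of them outlined, and the untreated list has 9.

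Widths of shared H3K4me3 peaks were similar in the 2 conditions. Among 16153 pairs the median log2 ratio of treated to untreated width was -0.02 with a standard deviation of 0.33 across pairs, and 46.8% of pairs were wider in treated cells. Across pairs, which are not independent replicates, log2 widths had a Pearson correlation of 0.905 and a Spearman correlation of 0.913. At least a 2-fold difference was seen in 183 pairs that were wider in treated cells and 84 that were wider in untreated cells. The largest ratio in favour of treated cells was on chromosome 9, where a treated peak of 3432 bp (62991756 to 62995187) faced an untreated peak of 583 bp, a 5.89-fold difference. It was followed by chromosome 4, 82692840 to 82698811, with 5972 against 1023 bp, and chromosome 11, 83663214 to 83667597, with 4384 against 839 bp. In favour of untreated cells the largest ratio was on chromosome 1, 10707103 to 10710602, with 3500 bp untreated against 768 bp treated, a 4.56-fold difference. Chromosome 5, 137545311 to 137548412, followed with 3102 against 706 bp.

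The treated list held fewer H3K27me3 peaks than the untreated list, and few peaks were at the same place in both. The lists held 821 treated and 1242 untreated peaks, with median widths of 149 and 211.5 bp, below the 600 bp to which the chromatin was sheared on average. Input peaks had median widths of 146 and 142 bp. Of the treated H3K27me3 peaks 29.4% (26.3 to 32.6) overlapped an untreated one, and of the untreated peaks 19.5% (17.4 to 21.8) overlapped a treated one. Most of these shared peaks also overlapped an input peak. Without input-overlapping peaks the shares were 7.50% (44 of 587) and 4.40% (44 of 999). Of these, peaks that overlapped no H3K4me3 peak recurred at 3.05% (12 of 394) in treated and 2.81% (12 of 427) in untreated cells. Those that overlapped an H3K4me3 peak of either condition recurred at 16.6% (32 of 193) and 5.59% (32 of 572). An input peak of either condition overlapped 28.5% of treated and 19.6% of untreated H3K27me3 peaks, against 0.841% and 0.880% of H3K4me3 peaks. The 2 input lists overlapped each other at 43.4% of treated and 35.7% of untreated input peaks. H3K27me3 peaks thus recurred less often than input peaks, and the lists alone show neither a loss nor a move of the mark.

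Among treated-only H3K27me3 peaks without an input peak, the widest was at chromosome 8, 109125731 to 109127562 (1832 bp, with H3K4me3 in both conditions). Next came chromosome 11, 94814972 to 94816075 (1104 bp, with H3K4me3 in treated cells only), and chromosome 7, 138683935 to 138684686 (752 bp). They were followed by chromosome 11, 94814010 to 94814750 (741 bp, with H3K4me3 in treated cells only), and chromosome 1, 57036117 to 57036791 (675 bp). Those on chromosomes 7 and 1 overlapped no H3K4me3 peak. The peak on chromosome 8 lay 154 bp from an untreated H3K27me3 peak. Among untreated-only H3K27me3 peaks without an input peak, the widest were at chromosome 11, 96878934 to 96880827 (1894 bp), and chromosome Y, 2884798 to 2886496 (1699 bp). Next came chromosome 10, 126516356 to 126518025 (1670 bp), chromosome 15, 37162459 to 37163896 (1438 bp), and chromosome 1, 78306735 to 78308004 (1270 bp). With input-overlapping peaks kept, the widest untreated-only peak was 4183 bp. Those on chromosomes 10, 15 and 1 overlapped H3K4me3 peaks of both conditions. The peaks on chromosomes Y and 10 lay 553 and 259 bp from a treated H3K27me3 peak.

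H3K27me3 peaks often overlapped H3K4me3 peaks of the same condition, in untreated cells more often than input peaks did. Untreated H3K27me3 peaks overlapped the treated H3K4me3 list more often than that of their own condition. Within the same condition the share was 47.5% (44.7 to 50.3) of untreated and 38.6% (35.3 to 42.0) of treated H3K27me3 peaks. Random placement gave a median of 2.01% and 1.71%. Input peaks also overlapped H3K4me3 peaks, at 26.5% (23.4 to 29.8) in untreated and 30.1% (26.6 to 33.9) in treated cells. Without H3K27me3 peaks that overlap an input peak the shares were 45.6% (42.6 to 48.7) in untreated and 31.3% (27.7 to 35.2) in treated cells, so the treated share was then not separated from that of treated input. H3K27me3 peaks that overlapped H3K4me3 peaks were wider than the others, with a median of 286.5 against 158 bp in untreated and 189 against 145 bp in treated cells. Input peaks differed in the same direction, with 152.5 against 141 bp in untreated and 164 against 144 bp in treated cells, and a wider peak is more likely to meet the 1 bp rule. Across conditions, 56.2% (53.4 to 58.9) of untreated H3K27me3 peaks overlapped a treated H3K4me3 peak, and 56.3% (53.2 to 59.3) without input-overlapping peaks. Of treated H3K27me3 peaks, 32.5% (29.4 to 35.8) overlapped an untreated H3K4me3 peak. Of 740 untreated input peaks, 200 overlapped a treated and 196 an untreated H3K4me3 peak. The cause of the higher share across conditions was not tested. Of the 999 untreated H3K27me3 peaks without an input peak, 446 overlapped H3K4me3 in both conditions, 116 in treated cells only, 10 in untreated cells only and 427 in neither. Of the 587 treated ones the numbers were 131, 53, 9 and 394.

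**Figure D3:**
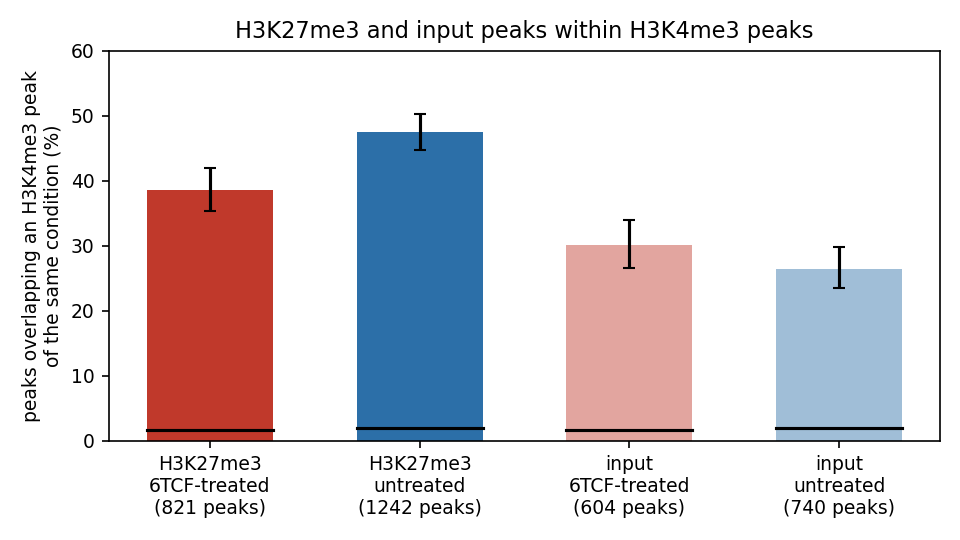
Share of H3K27me3 peaks (full colour) and input peaks (pale) that overlap an H3K4me3 peak of the same condition, in percent, for treated (red) and untreated (blue) cells, 1 library each. Error bars are 95% Wilson intervals and black lines the median of random placements. H3K27me3 stands at 38.6% and 47.5%, input at 30.1% and 26.5%, and without input-overlapping peaks, not drawn, H3K27me3 is at 31.3% and 45.6%. Overlap across conditions, not drawn, is 32.5% for treated and 56.2% for untreated H3K27me3 peaks.

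H3K4me3 peaks were wider in the treated list at regions that carried an H3K27me3 peak. This comparison was not part of the design and was chosen after the pattern had been seen in the same lists. Among 395 pairs with an untreated H3K27me3 peak, 351 (88.9%) were wider in treated cells, with a median width of 2005 against 1588 bp. Their median log2 ratio was 0.26 (95% bootstrap interval 0.22 to 0.31), a 1.19-fold difference, against -0.02 for all other pairs. None of 10000 random sets matched on mean width reached that median, and the highest was 0.07. For the 124 pairs with a treated H3K27me3 peak the median was 0.19 (0.14 to 0.24), 98 of them (79.0%) were wider in treated cells, and the highest random set was 0.11. Pairs with an untreated input peak had a median of 0.04 (0.01 to 0.07, 108 pairs), and those with a treated input peak 0.03 (91 pairs). In the 5 pairs with the widest untreated H3K27me3 peaks the log2 ratio was between 0.12 and 1.41. At chromosome 15, 37161897 to 37164725, the H3K4me3 peak was 2829 bp in treated and 1066 bp in untreated cells, and both overlapped an untreated H3K27me3 peak of 1438 bp. At chromosome 2, 122122844 to 122125254, the widths were 2411 and 975 bp, with an untreated H3K27me3 peak of 1250 bp. The widest of these H3K27me3 peaks, 1670 bp on chromosome 10, overlapped a pair of 2114 and 1950 bp and extended past the end of both.

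**Figure D4:**
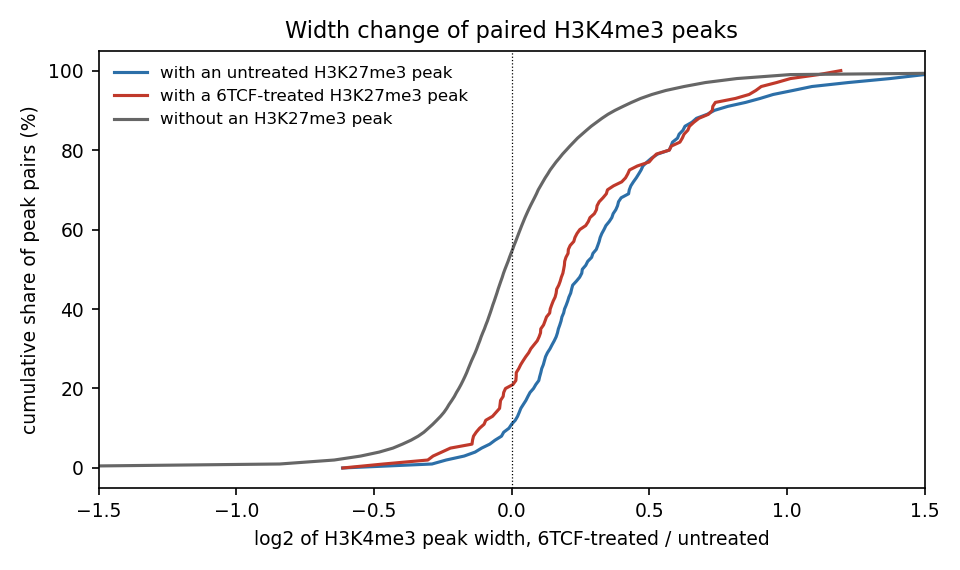
Cumulative share of H3K4me3 peak pairs (percent) by the log2 ratio of treated to untreated peak width, for pairs with an untreated H3K27me3 peak (blue, 395 pairs), with a treated one (red, 124 pairs) or with neither (grey). The blue and red curves lie to the right of the grey one, with medians of 0.26 and 0.19.

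H3K4me3 peaks listed only in treated cells overlapped untreated H3K27me3 peaks at nearly the rate of shared peaks before any adjustment for width. Of 1839 treated-only H3K4me3 peaks without an input peak, 51 (2.77%, 2.12 to 3.63) overlapped an untreated H3K27me3 peak, against 2.78% (2.54 to 3.04) of 16193 shared peaks. Of 800 untreated-only H3K4me3 peaks, 7 (0.875%, 0.424 to 1.80) did, against 2.49% (2.26 to 2.74) of 16217 shared peaks. Treated H3K27me3 peaks were overlapped by 19 treated-only H3K4me3 peaks (1.03%, 0.662 to 1.61), against 0.951% of shared ones. They were overlapped by 5 untreated-only peaks (0.625%, 0.267 to 1.45), against 0.789% of shared ones, so neither share was separated from that of shared peaks. Peaks in 1 list only are narrower than shared peaks, and the result of matching on width, chosen after these shares were seen, depended on which width of the shared peaks was used. The 51 treated-only peaks stood against a median of 27 (central 95% of 10000 sets, 18 to 38) with the treated width, 39 (28 to 52) with the mean width of the pair and 67 (52 to 83) with the untreated width. The 7 untreated-only peaks stood against 23 (14 to 33) with the untreated width, 15 (8 to 22) with the mean width and 11 (5 to 18) with the treated width. In 49 regions H3K4me3 was listed in treated cells only and H3K27me3 in untreated cells only, and the reverse was found in 5. These came from 1839 treated-only and 800 untreated-only H3K4me3 peaks and from H3K27me3 lists of unequal length. Of the H3K27me3 peaks without an input peak, 955 of 999 untreated and 543 of 587 treated ones were in 1 list only. The 49 regions therefore largely restate the 51 overlaps above. The widest H3K4me3 peaks among the 49 were at chromosome 11, 75006451 to 75009207 (2757 bp), chromosome 7, 17059639 to 17062325 (2687 bp), and chromosome 9, 59986852 to 59989458 (2607 bp), with H3K27me3 peaks of 771, 530 and 216 bp.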

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

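The tests of H3K27me3 recurrence and width below were chosen after the result was seen. The number of listed peaks moved in opposite directions for the 2 marks. H3K4me3 had 1017 more peaks in treated than in untreated cells, while for H3K27me3 the treated minus untreated difference was -421 peaks. The input lists moved in the direction of H3K27me3, with 604 peaks in treated and 740 in untreated cells. With 1 library per group the difference between the marks was not tested.

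The lower number of treated H3K27me3 peaks could come from a weaker yield or lower depth of that library, which would leave the most enriched untreated peaks to recur in it. With width as a stand-in, which does not measure enrichment, the share that recurred among the 999 untreated peaks without an input peak was 7.20% (95% Wilson interval 4.60 to 11.1) in the widest 25% and 4.72% (2.72 to 8.07) in the narrowest, so the test does not decide. H3K27me3 peaks that overlapped neither an input peak nor an H3K4me3 peak had nearly the width of input peaks, with a ratio of 1.06 in untreated and 0.993 in treated cells. This is consistent with background making up part of that class, though weakly enriched regions could be as narrow. The treatment cannot be told apart from the yield of a single library, and the antibody named in the labels stays unsettled.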

How the results depend on the processing

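The alternatives based on peak width, those of the width ratio and the removal of mitochondrial peaks were chosen after seeing the data. Of the 53 alternatives run 33 stayed within the 95% interval, or within 1.5 times a count, and 20 moved. Counts and shares cannot change sign, and the width ratios kept theirs. Of those set before the data were examined 22 stayed and 6 moved, and of those added later 11 stayed and 14 moved. Counting H3K27me3 peaks up to 1 kb apart as shared gave shares of 37.3% of treated and 25.3% of untreated peaks, and removing input-overlapping peaks gave 7.50% and 4.40%. That removal, applied to the H3K4me3 list as well and not to the H3K27me3 list alone (31.3%), gave a share of treated H3K27me3 peaks that overlapped H3K4me3 of 31.0%, and an overlap of at least 50% of the shorter peak gave 43.2% in untreated cells. Without the narrowest 25% of each list there were 1225 treated-only and 465 untreated-only H3K4me3 peaks, with 91.0% and 96.4% shared. The H3K27me3 shares were then 21.1% and 13.9%, and 28.3% of treated and 35.2% of untreated H3K27me3 peaks overlapped H3K4me3. Equal numbers of widest peaks gave 1226 treated-only and 1195 untreated-only H3K4me3 peaks, with 92.9% and 93.0% shared, and H3K27me3 shares of 15.5% and 15.2%; equal lists force nearly equal numbers in 1 list only. With H3K27me3 peaks wider than the median, the median log2 width ratio at untreated H3K27me3 peaks was 0.31. Other width matching changes the random sets and not that ratio, and under it 0 of 1000 sets reached the observed median for either H3K27me3 list. Apart from the input removal and the equal lists, the cause of the shifts was not tested. Alternatives based on score, on promoter windows and on gene lists were not run, because the files used here give no score and no annotation of their build was used. No paired analysis was possible because each group has 1 library, and no library could be left out. Unknown depth limits every count of peaks in 1 list only.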

Other observations

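In this part, the expected number of partners over the length limit was set down as a test before it was computed, after the excess of wide peaks in 1 list only had been noticed; all other tests and all comparisons of chromosomes were chosen after the result was seen. Over all chromosomes, 1854 of 18185 treated and 812 of 17168 untreated H3K4me3 peaks were in 1 list only. H3K4me3 peaks on the X chromosome were in 1 list only at a rate of 7.03% (41 of 583, 95% Wilson interval 5.23 to 9.40) in treated and 3.56% (20 of 562, 2.32 to 5.43) in untreated cells. In the treated list only chromosome Y, with 0 of 9, was lower. In the untreated list chromosomes 19 (3.19%), 16 (3.49%) and 11 (3.53%) were lower than X. Among the autosomes the rate was highest on chromosome 18 in both lists, at 12.5% (67 of 534, 10.0 to 15.6) in treated and 7.50% (38 of 507, 5.51 to 10.1) in untreated cells. On chromosome Y the H3K4me3 lists held 9 treated and 10 untreated peaks, the H3K27me3 lists 35 and 39, and the input lists 52 and 50.

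Mitochondrial DNA gave 4 H3K4me3 peaks and 5 H3K27me3 peaks in untreated cells, and 0 of either in treated cells. Both input lists held 3 mitochondrial peaks, which covered 9737 bp in treated and 9732 bp in untreated cells. All 4 of the untreated H3K4me3 peaks and 4 of the 5 H3K27me3 peaks overlapped them. With the input lists taken as background, these overlapping peaks are not evidence of either mark. Why the treated lists lacked mitochondrial peaks was not tested.

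Wide H3K4me3 peaks in 1 list only may reflect an upper length limit of the lists. From the fall in number between 5 and 8 kb, 36.4 peaks over 9151 bp would be expected in the 2 lists together, and 0 are listed. From the width ratios of pairs of 4 to 6 kb, 33.8 peaks over 7 kb would have a partner over that length, against 22 in 1 list only (exact 95% Poisson interval 13.8 to 33.3), so the expected number lies just above the interval and that test does not decide. As to background shared with the input, 0% of the 22 peaks overlapped an input peak (upper 95% Wilson limit 14.9%). Of all H3K4me3 peaks only 0.841% of treated and 0.880% of untreated ones did. Input peaks had median widths of 146 and 142 bp, so broad background might not be listed among them. The test therefore does not decide. The treatment stays open for single regions and was not tested against the limit.

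The greater H3K4me3 width in treated cells at H3K27me3 peaks is a pattern found and tested on the same lists. A general widening is argued against by a median log2 ratio of -0.0236 in pairs without an untreated H3K27me3 peak, and a change shared by all narrower peaks by 0 of 10000 width-matched random sets reaching the observed median. Carry-over of H3K4me3 DNA into the H3K27me3 library would favour the most enriched H3K4me3 peaks; pairs with an untreated H3K27me3 peak had a median geometric mean width of 1746 bp (1691 to 1841), against 2187 bp in other pairs, but width does not measure enrichment and carry-over stays open. Pairs with an untreated input peak had a median of 0.0426, with an interval below that of the H3K27me3 pairs. The treatment, GC content, antibody identity and differences in yield between single libraries were not tested and stay open, and no amount of H3K4me3 was measured, only the width of listed peaks.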
